A study of Mus musculus with 10 samples.

How the data were processed

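Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and tags it for sequencing, in 10 libraries from adipocytes differentiated from MAP cells, an immortalized mouse adipocyte progenitor line. The libraries formed 5 groups of 2: vehicle control, forskolin for 4 hours, forskolin for 1 day, forskolin for 3 days, and rosiglitazone for 3 days. Per the labels, treatment of the differentiated adipocytes was given at day 7 to 8, nuclei were released by homogenization and sorted on a DNA dye, 10000 nuclei went into each library, and libraries were amplified for 12 cycles and sequenced as pairs. Whether the 2 libraries of a group came from separate cultures is not stated. The tests of peaks and genes rest on the spread between libraries within groups, pooled over the 5 groups and shared across peaks or genes. They may therefore not cover the spread between cultures.

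The deposited table gives raw counts, without normalization, for 122984 peaks that do not overlap (median width 358 bp), with 1 column per library. The column names carry the group and a running number, S1 to S10, and these numbers name the libraries here. They do not tie a column to a labelled replicate, so no pairing between groups was used. The labels name fastp, Bowtie2, SAMtools, Picard, MACS2, featureCounts and deepTools as the authors' tools, without versions, and the mouse builds GRCm38 and mm10. Whether peaks were called per library or on pooled reads, whether reads or fragments were counted, and how duplicates and the transposase offset were handled is not given in the sources used here. Total counts in peaks ran from 10410233 to 18935287 per library. All intervals on shares and ratios cover counting error only.

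Gene positions came from the RefSeq annotation of GRCm38.p6, which was at hand as a table of gene bounds without strand. A peak within 1 kb of either annotated end of a protein-coding gene was called a gene-end peak, which stands in for a promoter peak and also takes in the other end of the gene. Only the outer bounds of each gene were used, so peaks at start sites inside them counted as gene body. Gene-end peaks can therefore miss a promoter. Other peaks were assigned to the gene body that held them, or else to the nearest gene end within 50 kb. By this rule 13.2% of peaks were gene-end peaks, 45.0% lay in gene bodies, 32.0% lay outside genes with a gene end within 100 kb, and 9.76% had none within that distance. The plan had named the nearest transcription start site, which needs the strand. Transcription factor motifs and GC content were not examined, because no genome sequence was at hand.

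Peaks were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests with robust dispersions, TMM factors and the default filter by expression, in 1 fit over all 10 libraries. This left 118954 peaks. A peak was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested peaks. Standard errors (SE) of log2 fold changes were derived from the F statistic. Counts summed over all peaks assigned to a gene gave gene accessibility, tested in the same way for 16998 genes with the library sizes and TMM factors of the peak table. Levels are CPM, the counts scaled to library size after TMM, as mean ± SD of 2 libraries. The biological coefficient of variation, taken as the square root of the median dispersion over peaks in the fit, was 0.164. The comparisons were each treatment with control, forskolin with rosiglitazone at 3 days, and the forskolin times with each other.

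A set of 24 gene lists was fixed before the data were examined, as were the comparisons, tests, thresholds and the rule for naming genes. Every list member was found in the annotation except Mx1 and Mx2 of the interferon list. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, first with the preset correlation of 0.01 and then with an estimated correlation, and with fry. Adjusted p values of lists are over the 24 lists, and single members are also given adjusted over the list alone.

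Genes and peaks were named by rule for each treatment against control and for forskolin against rosiglitazone. The first part took called peaks whose 2 libraries of one group both lay beyond the 2 of the other and whose mean level was at or above the median. Of these, the 5 with the largest positive and the 5 with the largest negative log2 fold change were named, at most 1 per nearest gene. The next part took the 4 members with the smallest adjusted p from each list that passed camera with the preset correlation, and always from the thermogenic, cAMP response and PPAR target lists. Always included were Ucp1, Ppargc1a, Cidea, Dio2, Nr4a1, Pde4d, Pparg, Adipoq, Fabp4, Lep and Pdk4, by gene, gene-end peak and most changed peak. Riken, Gm and olfactory receptor models were skipped. A few genes that the rule names are not reported here. Other genes are named where the text says that they were chosen after their values were seen.

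The procedure was tested on simulated data with the mean level of each feature, the dispersions of the fit, 200 changed features per fit and no other change. Among simulated peaks with a 4-fold change, 66.7% to 78.8% were called, and 31.3% to 40.3% of those with a 2-fold change. Between 1 and 4 of the 118754 unchanged peaks were called. Counts were drawn independently from the model that the test assumes. Shifts of many peaks at once between libraries, as in the share of counts at gene ends, were not simulated. The simulations therefore cannot tell how many false calls such shifts cause. For genes with a 1.5-fold change, 68.7% to 79.1% were called. Overlaps between treatments that share the control libraries were set beside 100 simulations in which no group differed.

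Alternatives were RLE factors, library size alone, trended offsets, DESeq2 1.42.0, no count filter and a stricter one, only the 2 groups compared, assignment distances of 10 kb and 100 kb, gene ends within 3 kb, gene-end peaks only, an estimated list correlation, and leaving out each library in turn. With 1 library left in a group, the fit assumed that it varied like the other groups. Thinning every library to the lowest total, leaving out the 10 highest peaks, library sizes from gene-end peaks, and trended offsets for genes, lists and gene-end shares were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.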

Results

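The count table held chromatin accessibility in 122984 peaks for 10 libraries of adipocytes made from MAP cells, in 5 groups of 2. Forskolin activates adenylyl cyclase and so raises cAMP, the messenger of adrenergic signals in adipocytes. Rosiglitazone is an agonist of the nuclear receptor PPARγ. The labels give the induction of adipocyte browning as the purpose of both treatments, and they list rosiglitazone in the differentiation medium of every group, control included. Total counts in peaks were 10410233 and 13055443 in the control libraries S1 and S2. They were 15062740 and 16519865 after 4 hours of forskolin (S3, S4), and 17002986 and 18935287 after 1 day (S5, S6). After 3 days they were 16287650 and 13031199 with forskolin (S7, S8), and 14219842 and 16296924 with rosiglitazone (S9, S10).

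On the first principal component, which held 44.1% of the variance, the controls scored −121 and −130 and the rosiglitazone libraries −162 and −164. The forskolin libraries scored 164 and 137 at 4 hours, 89.2 and 80.2 at 1 day, and 65.3 and 40.5 at 3 days. Across peaks, which are not independent replicates, Pearson's r of log2 CPM within groups was 0.942 for control, 0.958 for 4 hours, 0.964 for 1 day, 0.952 for 3 days and 0.958 for rosiglitazone. A chi-square of the counts of the 2 libraries of a group, over its degrees of freedom, ranked the groups otherwise. It was 2.22 for control, 2.37 for 4 hours, 2.35 for 1 day and 2.23 for rosiglitazone. For 3 days it was 3.37, so by this measure S7 and S8 differed most. Between control and 4 hours of forskolin r was 0.852 to 0.871, between control and rosiglitazone 0.917 to 0.931, and between 1 and 3 days of forskolin 0.945 to 0.959. The 3-day library S7 was closer to the 1-day libraries S5 (0.957) and S6 (0.959) than to S8 (0.952). In all 99 calls on named genes, both libraries of one group lay beyond both libraries of the other; for the largest changes among named peaks the naming rule required this. A joint test of the 3 forskolin times against control called 38936 peaks (32.7% of those tested).

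**Figure D1:**
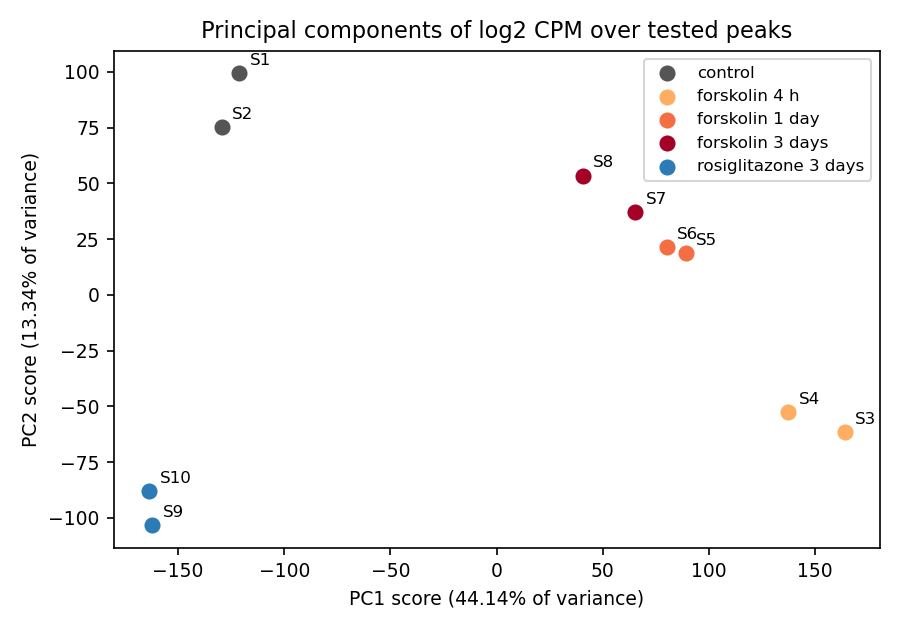
Scores of the 10 libraries on the first and second principal components of log2 CPM, which hold 44.1% and 13.3% of the variance; each point is a library, coloured by group. The 4-hour forskolin libraries lie farthest from the controls on the first component (164 and 137 against −121 and −130), and the 1-day and 3-day libraries lie between.

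The comparison of 4 hours of forskolin with control asked which chromatin opened or closed soon after cAMP was raised. The phosphodiesterase genes Pde4d, Pde4b and Pde10a rose, while Pde3b (0.18, adjusted p = 0.229) did not pass. The naming rule did not pick Pde3b, which was chosen after the values were seen. Also risen were Ppargc1a, which encodes a coactivator of thermogenic genes, Plin2, a lipid droplet gene, and Ucp1, the uncoupling protein of brown fat. The β3-adrenergic receptor gene Adrb3 fell, as did the interferon response genes Irf1 and Ifit2. Accessibility of Pde4d (chromosome 13, 108654177 to 109955969) rose from 279 ± 8.11 to 461 ± 11.3 CPM (log2 fold change 0.72, SE 0.049, adjusted p = 1.75e-09), and 37 of its 89 tested peaks rose. For Pde4b (chromosome 4, 102087332 to 102607275) the level rose from 90.6 ± 3.82 to 170 ± 13.8 CPM (0.91, SE 0.074, adjusted p = 1.55e-08). Ppargc1a (chromosome 5, 51454249 to 52115853) rose from 230 ± 19.8 to 304 ± 5.56 CPM (0.40, SE 0.06, adjusted p = 3.35e-05). With gene-end peaks only its change was −0.30, without a call, so its other peaks carried the rise. These take in any start site inside the wide bounds of the gene, so the gene-end value does not show how its promoters changed. Ucp1 (chromosome 8, 83290348 to 83298456) rose from 4.04 ± 0.571 to 6.85 ± 0.546 CPM (0.77, SE 0.228, adjusted p = 0.0126). Its adjusted p was 0.14 without S2 and 0.0863 without S3, and ran from 0.00444 to 0.14 over all its alternatives. Adrb3 (chromosome 8, 27225776 to 27230845) fell from 26.6 ± 0.479 to 12.9 ± 2.56 CPM (−1.04, SE 0.137, adjusted p = 7.07e-06). Irf1 fell by 0.57 on the log2 scale (SE 0.061, adjusted p = 5.73e-07) and Ifit2 by 1.11 (SE 0.133, adjusted p = 2.32e-06). Csf1r, a macrophage marker, rose from 8.14 ± 1.23 to 22.7 ± 1.28 CPM (1.47, SE 0.152, adjusted p = 3.63e-07). The log2 fold changes of Plin2 (0.72) and Pde10a (0.62) passed the test too, as did those of Lep (−0.45) and Cebpa (−0.51); the calls on Plin2 and Cebpa ended with gene-end peaks only. Fabp4 rose by 0.27 (adjusted p = 0.00224), a call that ended without S4 (0.0556) and with gene-end peaks only (−0.11, adjusted p = 0.459), the alternatives starting at 8.69e-06. The log2 fold changes of Cidea (0.01), Dio2 (0.39), Pparg (0.04), Adipoq (−0.12), Pdk4 (−0.09) and Nr4a1 (0.15) did not pass, although Nr4a1 passed with library size alone (adjusted p = 0.000863) and with trended offsets (0.0014), the range over its alternatives being 0.000863 to 0.733. With gene-end peaks only Adipoq fell by 0.83 and Pdk4 by 0.34, and both passed.

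At 4 hours 22005 peaks rose and 15403 fell, 31.4% of those tested, and 15715 and 6871 of these changed at least 2-fold. Of the calls, 58.8% were rises, and 68.9% with library size alone. With library size alone the median log2 fold change of all tested peaks was 0.10 at 4 hours, 0.19 after 1 day, 0.11 after 3 days and 0.10 with rosiglitazone. With TMM factors it was −0.004 at 4 hours and 0.04 after 1 day. Fewer peaks were called without S2 (23512) and without S3 (23576). For genes, 2133 rose and 3931 fell, so 35.2% of calls were rises. The majority turned with the scaling, to 57.0% rises with library size alone and 57.8% with trended offsets. Gene calls came to 2781 without S2, 2853 without S3 and 4022 without S4. Among named peaks the largest rise was in the body of Mitf (chromosome 6, 97921401 to 97921917), from 0.0826 ± 0.117 to 6.47 ± 0.523 CPM (adjusted p = 5.22e-15). The control level rested on 2 counts over both libraries against 205 counts at 4 hours, a ratio of 71 with a 95% counting interval of 19.4 to 590. A peak in the body of Rorb (chromosome 19, 19016721 to 19017514) rose from 0.225 ± 0.0324 to 8.05 ± 1.16 CPM. The largest fall was at Vac14 (chromosome 8, 110663118 to 110663660), from 29.1 ± 3.39 to 3.63 ± 0.672 CPM (−3.00, SE 0.184). The most changed peak nearest to Ucp1 (chromosome 8, 83287735 to 83288017) rose by 2.03, and one in Ppargc1a (chromosome 5, 51867963 to 51868802) by 1.70. The Lep gene-end peak fell by 1.56.

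Of the 24 gene lists, 3 passed camera at 4 hours with the preset correlation, and none in limma with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 4. The interferon list (19 genes) was lower (adjusted p = 0.0272, median log2 fold change −0.41, 9 genes fallen and none risen over all genes, and 9 fallen adjusted over the list alone); adjusted p = 0.304 with an estimated correlation, the highest of its alternatives, with 0.00183 the lowest. The macrophage and immune list (12 genes; adjusted p = 0.0272, median 0.28, 4 risen and 1 fallen both ways) and the cAMP response list (27 genes; adjusted p = 0.0272, median 0.06, 4 risen and 2 fallen, and 4 and 1 adjusted over the list alone) were higher; adjusted p = 0.304 and 0.814 with an estimated correlation. At the level of peaks, 138 of the 412 peaks at cAMP response genes rose and 29 fell, and many of the risen peaks lay at Pde4d (37), Pde10a (22), Pde4b (19) and Ppargc1a (14). With the preset correlation 2 lists passed without S2 and 1 without S4. The adjusted p of the cAMP list was 0.0688 without S1 and 0.0893 without S4 (range 0.00183 to 0.814). That of the macrophage list was 0.107 without S2, 0.0802 without S4 and 0.117 with trended offsets (range 3e-05 to 0.304). The interferon list passed without each library in turn. The thermogenic list had 7 risen and 5 fallen genes (adjusted p = 0.209), and the PPAR target list 3 and 9 (adjusted p = 0.614), each with the same counts adjusted over the list alone.

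**Figure D2:**
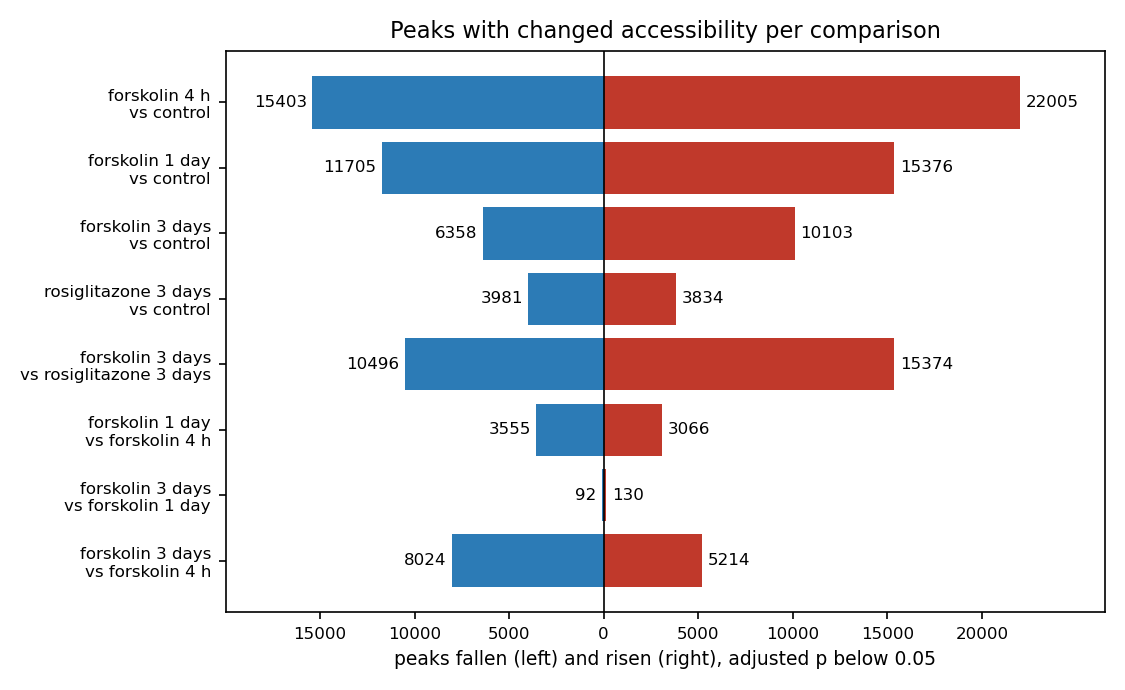
Number of peaks risen and fallen at adjusted p below 0.05 in each comparison. Counts with forskolin against control go from 22005 risen and 15403 fallen at 4 hours to 10103 and 6358 at 3 days, and rosiglitazone gives 3834 and 3981.

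After 1 day of forskolin, the comparison with control asked which changes were present once treatment had lasted overnight. Pde4b, Pde4d, Ppargc1a and Ucp1 were still above control and Adrb3 still below it. Fasn, which encodes fatty acid synthase, fell and Lcn2 rose. Fasn (chromosome 11, 120805958 to 120825166) fell from 112 to 67.2 CPM (−0.74, SE 0.104, adjusted p = 3.69e-05), and Acaca (−0.45), Acss2 (−0.46) and Pcx (−0.39) fell too. Lcn2, of the NF-κB inflammation list, rested on 1 peak and rose from 2.37 to 6.34 CPM (1.42, SE 0.254, adjusted p = 0.000314). Of the other genes that the rule named from that list, Ptgs2 rose (0.45), while Tnfaip3 (−0.40) and Nfkb2 (−0.43) fell. Ucp1 reached 8.11 ± 1.17 CPM (1.01, SE 0.221, adjusted p = 0.00148) and passed without each library in turn. Pde4b was up by 0.81, Pde4d by 0.44 and Ppargc1a by 0.38, and Adrb3 fell by 1.02. With gene-end peaks only the change of Ppargc1a was −0.07 and the call ended. Pde4b, at a larger fold change of 1.81, did not pass in that setting (adjusted p = 0.0573, the highest of its alternatives, with 1.3e-11 the lowest). Adipoq fell by 0.34 (adjusted p = 0.00535) and its gene-end peak (chromosome 16, 23146165 to 23146727) by 1.04. The call on the gene ended without S2 (adjusted p = 0.0968), with library size alone (0.0981) and with trended offsets (0.19, the highest of its alternatives, with 8.6e-06 the lowest). Pparg fell by 0.17 (adjusted p = 0.0285), a call lost under several alternatives, such as without S2 (0.201), S5 (0.0616) or S6 (0.193) and with library size alone (0.877, the highest; the lowest was 0.0127).

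At 1 day 15376 peaks rose and 11705 fell (22.8% of those tested). Rises were 56.8% of the calls, and 75.9% with library size alone. The calls came to 13929 without S2 and 14040 without S5. Among genes 1638 rose and 4742 fell, so 25.7% of calls were rises, against 60.2% with library size alone and 55.2% with trended offsets; without S2 2766 genes were called and without S5 2751. Of the peaks that fell, 39.2% (95% interval 38.3 to 40.1) were gene-end peaks, against 11.8% of uncalled peaks and 3.99% of risen peaks. The odds ratio of fallen against uncalled peaks was 4.82 by Fisher's exact test (two-sided), and 1.2 with trended offsets. At 4 hours the share was 24.1% of fallen peaks (odds ratio 1.95) and 4.06% of risen peaks. Of fallen peaks it was 12.1% with trended offsets (odds ratio 0.735) and 11.9% with gene-end library sizes (0.683), so that the direction against uncalled peaks turned. A peak at Slc25a15 rose from 1.2 to 14.7 CPM (3.67). The de novo lipogenesis list (20 genes) was lower at 1 day (camera adjusted p = 0.0395, median −0.25, 12 fallen and none risen over all genes, and 14 fallen adjusted over the list alone). Its adjusted p was 0.107 without S2, 0.0608 without S5 and 0.197 with trended offsets, and adjusted p = 0.702 with an estimated correlation was the highest of its alternatives, 0.0186 the lowest. The NF-κB inflammation list (25 genes) was higher (adjusted p = 0.0395, median 0.03, mean 0.16, 8 risen and 3 fallen, and 9 and 3 adjusted over the list alone). That call ended without S2 (0.074) and S5 (0.0608) and with assignment within 10 kb (0.0852); adjusted p = 0.59 with an estimated correlation was the highest and 0.0276 the lowest. With an estimated correlation none of the 24 lists passed camera in limma, 1 having an unadjusted p under 0.05, while fry called 10. The lists passing the preset test numbered 6 without S1, none without S2 or S5, and 3 without S6. The thermogenic list had 6 risen and 4 fallen genes (adjusted p = 0.0903; 7 and 4 adjusted over the list alone), and the PPAR target list 2 and 17 (adjusted p = 0.0903; 2 and 19), which passed without S1 (0.0186, the lowest of its alternatives, with 0.764 the highest). For the cAMP list (4 risen and 5 fallen both ways, adjusted p = 0.552) the median was −0.11 and the mean −0.02, while camera's direction was up.

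After 3 days of forskolin, the comparison with control asked what lasting treatment left changed. Adrb3 was still below control, and Ucp1, Ppargc1a and the phosphodiesterase genes Pde4b and Pde4d were still above it. Adrb3 fell to 11.6 ± 0.858 CPM (−1.21, SE 0.14, adjusted p = 1.64e-05), and a peak in its body (chromosome 8, 27228222 to 27228751) fell by 2.48. Ucp1 stood at 8.17 ± 1.54 CPM (1.01, SE 0.226, adjusted p = 0.00528), and without S2 its adjusted p was 0.0967, the highest of its alternatives (the lowest was 0.000972). Pde4b rose by 0.67 (adjusted p = 9.45e-06), Pde4d by 0.37 (adjusted p = 5.94e-05) and Ppargc1a by 0.32 (adjusted p = 0.00165). With gene-end peaks only neither Pde4b, at a larger fold change of 2.06, nor Ppargc1a, at 0.24, passed. Lep fell by 0.35 (adjusted p = 0.0104), a call that ended without S2 (0.203, the highest of its alternatives, with 0.00455 the lowest), with trended offsets (0.0534) and with assignment within 10 kb (0.116). The changes of Pparg (−0.06), Adipoq (−0.19), Fabp4 (0.03) and Nr4a1 (−0.09) did not pass, although the gene-end peak of Adipoq fell by 0.80.

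At 3 days 10103 peaks rose and 6358 fell (13.8% of those tested). Of the calls 61.4% were rises, and 75.6% with library size alone. These tests used a spread pooled over the 5 groups. With only the 2 groups compared in the fit, calls against control rose to 38248 at 4 hours, 28902 at 1 day and 8675 with rosiglitazone. At 3 days they fell from 16461 to 12603 in that setting, so the pooled spread made the 3-day calls more numerous. The calls came to 10728 without S1, 8562 without S2 and 8891 without S7. Among genes 922 rose and 1756 fell. Rises made up 34.4% of these, and 69.6% with library size alone, 66.7% with trended offsets and 55.7% without S2. Gene calls numbered 1395 without S1, 582 without S2, 1313 without S7 and 5255 without S8. Of the fallen peaks 17.6% were gene-end peaks (odds ratio 1.3 against uncalled peaks), and of the risen 4.29%; with trended offsets the share of fallen peaks was 8.36% and the odds ratio turned to 0.536, as it did with gene-end library sizes (0.631). The Mitf peak was also the largest rise at 3 days, at 5.15 ± 1.14 CPM. No list passed camera in limma with the preset correlation and all assigned peaks, where 6 of 24 had an unadjusted p under 0.05; with an estimated correlation 3 had, and fry called 1. The lists passing numbered 3 without S1, none without S2, 1 without S7 and 1 without S8. Closest was the interferon list (adjusted p = 0.0658, median −0.30, 6 fallen and none risen; 8 and 1 adjusted over the list alone), which passed without S1 (0.0309) and without S7 (0.0375), its alternatives running from 0.00127 to 0.379. The inflammation list (2 risen and 1 fallen; 3 and 2 adjusted over the list alone), the thermogenic list (6 risen and 1 fallen; 6 and 2) and the macrophage list (1 risen and 1 fallen both ways) followed, each at 0.0785. The macrophage list passed without S1 (0.0309) and without S8 (0.022), its alternatives running from 0.00946 to 0.608. With gene-end peaks only 6 lists passed: interferon (0.00127), macrophage (0.00946), and inflammation, thermogenic, cAMP, and bone and cartilage (0.0412 each). With trended offsets interferon (0.0195) and inflammation (0.0328) passed. Over their alternatives the highest values were 0.379 for inflammation, 0.541 for thermogenic, 0.915 for cAMP, and 0.983 for bone and cartilage. The cAMP list had 4 risen and 2 fallen genes (adjusted p = 0.292; 5 and 2 adjusted over the list alone) and the PPAR target list 3 and 8 (adjusted p = 0.511).

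**Figure D3:**
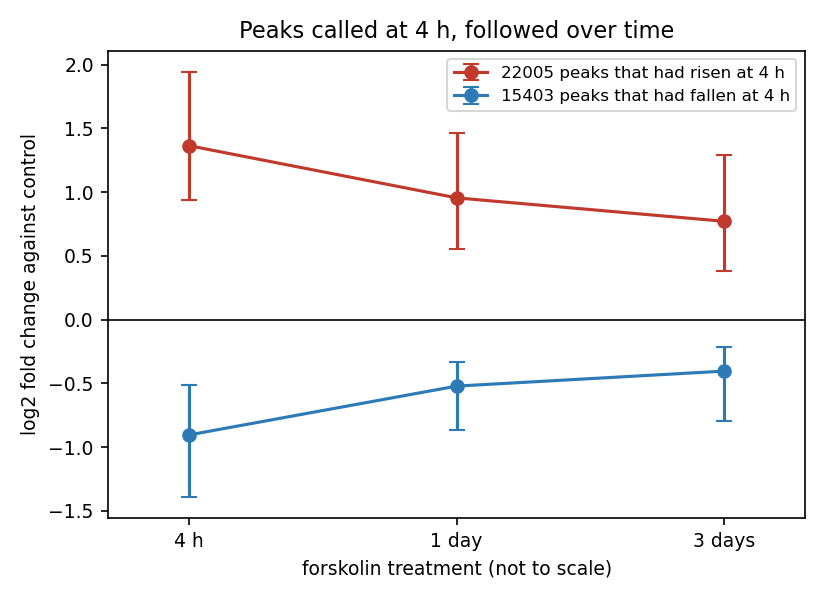
Log2 fold change against control at 4 hours, 1 day and 3 days of forskolin for the 22005 peaks that rose and the 15403 that fell at 4 hours. Points joined by lines are medians and bars span the quartiles. The median of the risen peaks goes from 1.36 at 4 hours to 0.77 at 3 days.

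The forskolin times were compared with each other to see how the 4-hour changes developed. Of the peaks that rose at 4 hours, 56.1% were also called above control at 1 day and 36.7% at 3 days. Their median log2 fold change was 1.36, 0.96 and 0.77 at the 3 times. A difference of 3 days from 4 hours back toward control was called in 29.3% of them (6442 peaks), and one farther from control in 72. For peaks fallen at 4 hours, 50.4% were called at 1 day and 29.2% at 3 days, with medians of −0.91, −0.52 and −0.40, and 21.2% (3260) had come back toward control. Of the peaks above control at 3 days, 80.0% (8083) had been called above it at 4 hours, where independent lists would share 1869. Both comparisons use the same controls: the covariance of their log2 fold changes across peaks was 0.592 and r 0.745, against 0.135 and 0.567 in simulations of unchanged groups that share them. Of all peaks called at 4 hours, risen or fallen, 33.6% were called the same way at 3 days. This persistence was 41.2% without S3, 17.4% without S7 and 28.3% without S2. At 1 day against 4 hours 3066 peaks were higher and 3555 lower, and 339 genes were higher and 581 lower. Rises were 46.3% of those peak calls, and 58.3% with library size alone. The peak calls fell to 2012 without S3, 2706 without S4, 2075 without S5 and 1982 without S6. At 3 days against 4 hours 5214 peaks were higher and 8024 lower, with 5165 calls without S3, 8003 without S4 and 7088 without S8. At 3 days against 1 day 130 peaks were higher and 92 lower; the count was 2975 without S7, 10 without S5, 23 without S6 and 5 without S8. Rises were 58.6% of these, 40.8% with library size alone and 89.5% with DESeq2. The genes called between 1 and 3 days were Dsg2 (0.60, SE 0.091, adjusted p = 0.0206) and Vmn1r238 (1.06, SE 0.174, adjusted p = 0.028), which are named because the count was 2.

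Rosiglitazone for 3 days was compared with control to find the chromatin that a PPARγ agonist opens in adipocytes exposed to it during differentiation. Whether the controls were free of rosiglitazone when collected is not given in the sources used here, so each change is relative to a control of unknown exposure. Fabp4, which encodes a fatty acid binding protein, rose, as did Cd36, Plin2, Hadhb, Cpt1b, Fgf21, Ucp1 and Ppargc1a. Fabp4 (chromosome 3, 10204342 to 10208616) rose from 142 ± 0.861 to 323 ± 2.49 CPM (1.19, SE 0.061, adjusted p = 2.91e-11), and 9 of its 10 tested peaks rose. Cd36 rose from 62.4 ± 3.12 to 119 ± 3.41 CPM (0.93, SE 0.088, adjusted p = 1.86e-06). Cpt1b (chromosome 15, 89416405 to 89425862) rested on 1 peak with a low control level. It rose from 0.583 ± 0.11 to 6.28 ± 0.116 CPM (3.39, SE 0.433, adjusted p = 8.8e-05). Hadhb rose by 1.04 (adjusted p = 8.97e-05), and Fgf21 from 2.77 ± 0.0582 to 9.05 ± 1.02 CPM (1.70, SE 0.265, adjusted p = 0.000487). Plin2 rose by 0.69 (adjusted p = 3.67e-06) and Ppargc1a by 0.36 (adjusted p = 0.000957); both calls ended with gene-end peaks only, where Ppargc1a changed by −0.12. Ucp1 reached 8.2 ± 0.078 CPM (1.03, SE 0.224, adjusted p = 0.00683). Its adjusted p was 0.131 without S2 and 0.0558 without S9, and ran from 0.00119 to 0.131 over its alternatives. Pdk4 rose by 0.40 (adjusted p = 0.000951), a call that ended with assignment within 10 kb (0.0506) and with gene-end peaks only (0.718, the highest of its alternatives, with 3.85e-07 the lowest). The changes of Pparg (−0.16), Adipoq (−0.10), Lep (−0.15) and Nr4a1 (−0.15) did not pass. The gene-end peak of Lep (chromosome 6, 29073526 to 29074436), at the upper bound of the gene and not shown to be its promoter, fell by 0.90 (adjusted p = 0.00268). That call ended without S2 and without S10. With gene-end peaks only Lep passed (adjusted p = 0.0175, the lowest of its alternatives, with 0.903 the highest).

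With rosiglitazone 3834 peaks rose and 3981 fell (6.57% of those tested). Rises were 49.1% of calls, and 68.6% with library size alone. The calls came to 3904 without S1, 3948 without S2, 3259 without S9 and 3983 without S10. Among genes 418 rose and 858 fell. Rises made up 32.8%, but 72.8% with library size alone and 51.4% with trended offsets; genes called were 561 without S1, 262 without S2, 243 without S9 and 544 without S10. A peak between genes (chromosome 8, 47768633 to 47769174) rose from 1.29 to 20.4 CPM (3.95), and one beside Fabp4 (chromosome 3, 10202195 to 10203293) from 12.5 to 57.6 CPM (2.20). Of the 24 lists 6 passed camera with the preset correlation, and none of them in limma with an estimated correlation, where 2 lists had an unadjusted p under 0.05; fry called 7. The PPAR target list (35 genes) had 15 risen and 2 fallen genes (adjusted p = 8.67e-08, median 0.20; 20 and 6 adjusted over the list alone), and the thermogenic list 8 risen and none fallen (27 genes; adjusted p = 8.43e-07, median 0.21; 10 and none adjusted over the list alone); adjusted p = 0.432 and 0.126 with an estimated correlation. The macrophage list (adjusted p = 0.00125, 3 risen; 4 adjusted over the list alone), the fatty acid oxidation list (31 genes; adjusted p = 0.00595, 3 risen; 4 adjusted over the list alone) and the glycolysis list (22 genes; adjusted p = 0.0272, 1 risen both ways) were higher; adjusted p = 0.126, 0.752 and 0.752 with an estimated correlation. The white-selective list (20 genes) was lower (adjusted p = 0.0113, 3 fallen; 5 adjusted over the list alone); adjusted p = 0.432 with an estimated correlation. The fatty acid oxidation call ended without S1 (0.0526), and the glycolysis call without S1 (0.162) and S10 (0.0597). The glycolysis call also ended with assignment within 10 kb (0.0752), and with gene-end peaks only the glycolysis (0.169), oxidation (0.12) and white-selective (0.0527) calls ended. The PPAR, thermogenic, macrophage and white-selective lists passed without each library in turn. The calls on the risen macrophage genes Cd74, Csf1r and Cd68 ended in each of these fits at similar folds, 0.96 to 1.00 for Cd74, 0.46 to 0.77 for Csf1r and 0.40 to 0.43 for Cd68. Their adjusted p values were 0.0813, 0.18 and 0.108 without S1, 0.152, 0.0697 and 0.199 without S2, 0.105, 0.094 and 0.193 without S9, and 0.0809, 0.125 and 0.0965 without S10. Over all alternatives they ran from 0.00637 to 0.157, 0.00622 to 0.931 and 0.0051 to 0.199. The value with an estimated correlation was in each case the highest of the list's alternatives, and the lowest were 1.18e-09, 0.00172, 2.26e-07, 0.00085, 0.000286 and 0.000286 for the PPAR, white-selective, thermogenic, macrophage, oxidation and glycolysis lists. The cAMP list had 2 risen and 6 fallen genes (adjusted p = 0.357).

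**Figure D4:**
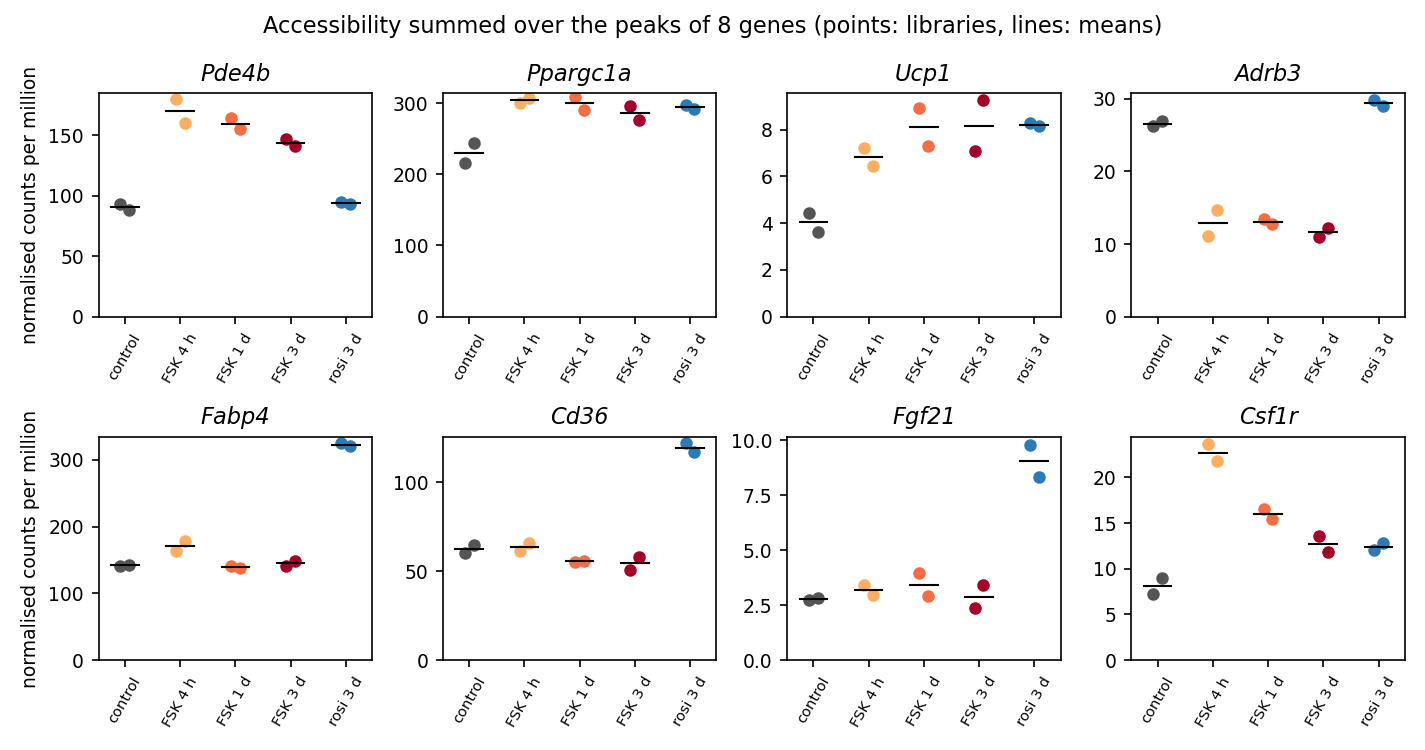
Accessibility of 8 genes in CPM for each library (points) with the mean of each group (lines); the genes were picked from the named genes after their values were seen. Pde4b is highest after 4 hours of forskolin (170 CPM on average against 90.6 in control) and Fabp4 after rosiglitazone (323 against 142).

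Forskolin and rosiglitazone were compared at 3 days to see whether both routes to browning opened the same chromatin. Ucp1 (−0.02, adjusted p = 0.96) and Ppargc1a (−0.04, adjusted p = 0.669) did not differ detectably between them in counts summed over the gene, although 6 of the 52 tested peaks of Ppargc1a were higher and 8 lower with forskolin. Fabp4, Cd36, Hadhb, Fgf21 and Adrb3 were lower with forskolin and Pde4b and Il6 higher. The log2 differences, forskolin minus rosiglitazone, were −1.16 for Fabp4 (adjusted p = 3.58e-11), −1.13 for Cd36 (4.02e-08), −1.55 for Hadhb (9.83e-08), −1.67 for Fgf21 (7.79e-05), −1.35 for Adrb3 (5.87e-07), 0.61 for Pde4b (5.08e-06) and 0.64 for Il6 (0.000108). With gene-end peaks only the difference of Pde4b was larger, 1.96, but did not pass (adjusted p = 0.0961, the highest of its alternatives, with 5.04e-08 the lowest). In all, 15374 peaks were higher with forskolin and 10496 lower, 21.7% of those tested, with 17094 calls without S7, 16687 without S9 and 16183 without S10. A peak on chromosome 10 at 100155553 was lower by 4.68, at 0.601 against 15.7 CPM. Among genes 1477 were higher and 1450 lower, so 50.5% of calls were rises, 60.2% with trended offsets, 46.7% with library size alone, 60.3% without S7 and 38.1% without S8; 1482 genes were called without S9 and 1457 without S10. The PPAR target list was lower with forskolin (1 risen and 21 fallen genes, camera adjusted p = 5.06e-07, median −0.34; 1 and 23 adjusted over the list alone). It passed without each library in turn, but not with an estimated correlation (adjusted p = 0.595, the highest of its alternatives, with 1.76e-08 the lowest). The inflammation list (8 risen and 1 fallen; 9 and 2 adjusted over the list alone) and the cAMP list (6 risen and none fallen; 6 and 1 adjusted over the list alone) were higher and the interferon list (3 fallen both ways) lower, each with adjusted p = 0.0386. With an estimated correlation none passed camera in limma (adjusted p = 0.504, 0.676 and 0.504 in this order, each the highest of its alternatives, with lowest values of 0.000127, 9.06e-05 and 0.00208); 2 lists had an unadjusted p under 0.05, while fry called 7. The inflammation call ended without S7 (0.051) and S10 (0.0525), the cAMP call without S7 (0.051), S8 (0.0771) and S9 (0.105). The interferon call ended without S7 (0.051), S8 (0.0852), S9 (0.0606) and S10 (0.0525). The thermogenic list had 6 lower genes and none higher (adjusted p = 0.0967; 7 lower adjusted over the list alone).

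Against their shared controls, both treatments at 3 days raised 1024 peaks and lowered 779 in common, 1803 in the same direction. Independent lists of these sizes would share 326 risen and 213 fallen. In opposite directions 526 peaks were called. Of the peaks that rose with rosiglitazone, 26.7% also rose after 3 days of forskolin. After 4 hours it was 39.4% (1511 peaks, where independent lists would share 709), and 839 peaks that rose after 4 hours of forskolin fell with rosiglitazone (736 for independent lists). The count in the same direction was 1002 without S1, 906 without S2, 1220 without S7, 873 without S9 and 1033 without S10. Across peaks, the covariance of the log2 fold changes was 0.169 and r was 0.301. Simulations of unchanged groups that share the same controls gave 0.135 and 0.564. In these simulations almost no peak was called at all, on average 0.02 with forskolin and 0.06 with rosiglitazone. They therefore cannot tell how far shared controls raise the number of shared calls.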

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

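The test with separate controls for the overlap of the 2 treatments, and the use of trended offsets, thinned libraries and gene-end library sizes for the gene-end share, were chosen only after those results had been seen.

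The values in this paragraph are differences between the forskolin effects at 2 times, each called by edgeR in the comparison of the times itself. After 1 day, these gene log2 fold changes were lower than at 4 hours: Csf1r −0.51, Fasn −0.39, Cd68 −0.39, Egr1 −0.38, Plin2 −0.37, Pcx −0.32, Ptgs2 −0.29, Fabp4 −0.29, Pde4d −0.29, Pde10a −0.27, Nr4a1 −0.23 and Pparg −0.21. They were higher for Slc29a1 (0.29), Irf1 (0.24) and Ppara (0.20). After 3 days the differences from 4 hours were −0.83 for Csf1r, −0.62 for Ptgs2, −0.47 for Plin2, −0.36 for Pde4d, −0.33 for Pde10a, −0.27 for Egr1, −0.24 for Fabp4, −0.24 for Nr4a1 and −0.24 for Pde4b. They were 0.82 for Lcn2, 0.55 for Cfd, 0.44 for Irf1 and 0.31 for Ppara. Among named peaks, the 1-day level was below the 4-hour level at Rorb (−1.44), Ttc39b (−1.34) and Znrf4 (−1.15). It was above it at Eml6 (1.93), Lmcd1 (1.82), Katnal1 (1.53), Mmd (1.27) and Vac14 (0.76). At 3 days the differences were −2.16 at Rorb, −2.10 at Ttc39b, −1.34 at Znrf4, −1.16 at Fam81a and −1.52 at a peak on chromosome 13 at 100950814. They were 2.75 at Eml6, 1.64 at Lmcd1, 1.56 at Katnal1, 1.52 at Mmd and 1.24 at Vac14. Most of the peaks that had risen most at 4 hours came down and those that had fallen most came up, as peaks picked for their extremes at 1 time also would by chance.

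The first pattern weighed was the excess of gene-end peaks among peaks that fell after 1 day of forskolin (odds ratio 4.82 against uncalled peaks). Deeper treated libraries are argued against as its cause, since thinning every library to the lowest total left an odds ratio of 4.81 (4.6 to 5.03). A plain loss of share to reads gained elsewhere is argued against as the whole cause, since library sizes taken from gene-end peaks left 2.33 (2.16 to 2.5). In that setting 3731 peaks were called as fallen, against 11705 as reported. Differences between libraries that depend on the level of a peak, such as signal over background, cannot be told apart from a biological closing of promoters, because with trended offsets the odds ratio was 1.2 (1.13 to 1.27), and such offsets would also remove a true change shared by high peaks. Control libraries held 45.1% and 46.6% of their counts at gene ends and the 1-day libraries 40.2% and 41.9%. Gene-end peaks were 13.2% of all peaks, so each held more counts on average and a small fall was easier to call there. No comparison of fallen with uncalled peaks matched on level was made.

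The next pattern was that accessibility gained at 4 hours was lower at 3 days. Selection of peaks on noise at 4 hours is argued against as the whole cause: in peaks called with 1 of the 4-hour libraries, the library left out still lay above the 3-day mean by a median of 0.473 or 0.573 on the log2 scale. The 3-day library S8, whose gene-end share (45%) was close to that of the controls, is argued against as the whole cause: without it the median log2 fold change of peaks risen at 4 hours still went from 1.34 at 4 hours to 0.81 at 3 days, against 1.36 and 0.77 with it. Without it 14.3% of these peaks were called back toward control, against 29.3% with it, at nearly the same fold and with 1 library less in the fit. A transient response to cAMP, for which the design gives 3 times, may account for the rest, as a hypothesis; a difference in culture age or handling between the times was not tested, since the labels give no collection dates.

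The last pattern was that forskolin and rosiglitazone at 3 days changed the same peaks more often than independent lists would. Shared control libraries give part of the covariance of log2 fold changes: in unchanged simulated groups it was 0.135, and the observed 0.169 was above that by 0.0343. The simulations cannot tell how many of the shared calls come from the controls, since almost no peak was called in them. Noise particular to each control library is argued against as the whole cause of the covariance. With 1 control library for forskolin and the other for rosiglitazone the covariance was 0.0434 or 0.0610, with r of 0.045 and 0.066. A deviation that both control libraries share stays in this test, so it cannot be told apart from a common response. The control libraries S1 and S2 had the lowest TMM factors, 0.9516 and 0.9275. A response common to both treatments may remain, as a hypothesis of modest size by these values. Time in culture that both treated groups share against control was not tested.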

How the results depend on the processing

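The alternatives with thinned libraries, without the 10 highest peaks, with gene-end library sizes, and with trended offsets for genes, lists and gene-end shares were chosen after the data had been seen. No paired analysis was possible because the columns carry a group and a running number but no link between groups; motif tests and their alternatives were not run, since no genome sequence was at hand. In simulations, 2.99% to 13.4% of peaks with a 1.5-fold change were called at these depths. Far fewer peaks were changed in them than were called against control in the data, which makes the adjusted p stricter. These shares therefore cannot tell how many small changes of single peaks went unseen in the data. At 1 day the median log2 fold change was −0.61 for the fallen peaks and 1.22 for the risen peaks. Leaving out 1 library at a time gave these ranges of called peaks: 23512 to 29032 at 4 hours of forskolin, 13929 to 20184 at 1 day, 8562 to 17298 at 3 days, 3259 to 3983 with rosiglitazone, and 16183 to 21528 for forskolin against rosiglitazone. For 1 day against 4 hours the range was 1982 to 2706, for 3 days against 1 day 5 to 2975, for 3 days against 4 hours 5165 to 10838, and for any forskolin time 26643 to 41926. Genes called ranged over 2781 to 4536, 2751 to 5101, 582 to 5255, 243 to 561 and 1457 to 3920 in the first 5 of these comparisons. Lists called ranged over 1 to 3, 0 to 6, 0 to 3, 4 to 8 and 1 to 3. Peaks changed in the same direction by both treatments ranged from 873 to 2606, and the persistence of 4-hour calls from 17.4% to 41.2%. Of 99 calls on named genes 29 ended in at least 1 of these fits, of 99 on named peaks 13, and of 15 on lists 9; none of these calls reversed. Fewer libraries lower the power of each fit, which is part of the cause of lower counts. DESeq2 called 9841 peaks at 3 days, 3691 with rosiglitazone, 16864 for forskolin against rosiglitazone, 2560 for 1 day against 4 hours, 38 for 3 days against 1 day and 6483 for 3 days against 4 hours, with an overlap of 747 peaks and a persistence of 27.5%. With only the 2 groups compared in the fit, 1 day against 4 hours gave 10614 peaks and 3 days against 1 day 130. That setting gave 12603 peaks for 3 days against control, 12489 for 3 days against 4 hours and 24443 for forskolin against rosiglitazone. Trended offsets gave 418 peaks for 3 days against 1 day, 1 list at 1 day and 2 at 3 days. The odds ratio of gene-end peaks among fallen peaks turned below 1 with trended offsets, to 0.735 at 4 hours, 0.536 at 3 days and 0.737 with rosiglitazone, and with gene-end library sizes, to 0.683 at 4 hours and 0.631 at 3 days. With rosiglitazone it was 1.03 with gene ends within 3 kb and 1.09 in thinned libraries, and neither passed. The gene-end peak of Pdk4 changed by 0.007 at 4 hours and 0.209 at 1 day with trended offsets, opposite to the value reported. Library size alone gave a persistence of 36.1%. With an estimated correlation the lists called were 0 at 4 hours, 1 day, with rosiglitazone and for forskolin against rosiglitazone, with 2, 1, 2 and 2 at an unadjusted p under 0.05 and 4, 10, 7 and 7 called by fry. Assignment within 10 kb left 1 list at 1 day. With gene-end peaks only, genes called were 2835 at 4 hours, 349 at 3 days, 210 with rosiglitazone and 609 for forskolin against rosiglitazone, and lists called were 4 at 1 day, 6 at 3 days, 3 with rosiglitazone and 8 for forskolin against rosiglitazone. This setting tests fewer peaks per gene. It also turned the direction of Ppargc1a at 4 hours (−0.30), 1 day (−0.073) and with rosiglitazone (−0.12), of Fabp4 at 4 hours (−0.11), of Plin2 at 1 day (−0.23), of Cxcl5 between the treatments (−0.086), and of the adipogenic transcription factor list between the treatments (adjusted p = 0.0463). For these results the cause was not tested. RLE factors kept the side of the threshold and the direction in all 139 results on named genes, and no count filter and leaving out the 10 highest peaks did so in all 136 results on named peaks each.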

Other observations

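The peaks and genes described in this part were chosen after their values were seen, while the lists were fixed beforehand; the tests of shared peaks against other lists than the PPAR list and against rosiglitazone alone were also chosen after that result was seen.

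Genes with many changed peaks gave the same names at several times. Pde4d had the most risen peaks with forskolin, 37 at 4 hours, 25 at 1 day and 19 at 3 days, followed at 4 hours by Lpp (23), Fndc3b (22) and Pde10a (22). Rad51b had the most fallen peaks at 4 hours (21) and at 1 day (17). With rosiglitazone Plin2 (12), Ppargc1a (11), Cd36 (10), and Chst11 and Fabp4 (9 each) led the risen peaks. Genes with more tested peaks have more chances to be counted here. The highest peak of the table lay on chromosome 1 (24611596 to 24616141) and took 2.03% of the counts on average. The 10 highest peaks together held 5.88% and 5.10% of counts in the controls S1 and S2 and 5.16% in S8. In the other libraries they held 3.48% to 4.02%. Whether these peaks reflect open chromatin or an artifact was not tested.

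A group of 702 peaks was above control at 3 days of forskolin and higher at 3 days than at 4 hours, and 630 of these were not called above control at 4 hours. They lay near 565 genes, with at most 3 peaks per gene, as at Antxr1 and Txnl4b.

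The lists not described with the comparisons gave the following at 4 hours of forskolin, as genes risen and fallen with camera's adjusted p at the preset correlation. The adipogenic transcription factor list (29 genes) had none risen and 10 fallen (0.176), and the cell cycle list (22 genes) none risen and 6 fallen (0.176). The lipolysis and Gs signalling list (26 genes) had 5 and 11 (0.59), the circadian clock list (19 genes) 1 and 8 (0.403), and the stress response list (21 genes) 3 and 6 (0.59). The progenitor list (23 genes) had 4 and 5 (0.59), the extracellular matrix list (31 genes) 9 and 9 (0.434), and the creatine and calcium cycling list (12 genes) 2 and 1 (0.909). In these last 3 lists the median and mean were below 0 while camera's direction, which is relative to all other genes, was up. Among lists of other cell types, the endothelial list had 4 and 1 (0.205), skeletal muscle 2 and 1 (0.434), mural cells 3 and 3 (0.565), neural cells 1 and 1 (0.59), mesothelial cells 4 and 0 (0.176), and bone and cartilage 3 and 1 (0.579; median 0.02, mean −0.15). None of these 14 lists passed at 1 day, 3 days or with rosiglitazone either, in camera with the preset correlation, all libraries, all assigned peaks and TMM factors; some did under an alternative, such as bone and cartilage at 3 days with gene-end peaks only (0.0412). After 1 day the circadian list had 1 risen and 11 fallen genes and the adipogenic transcription factor list none and 13 (both 0.0903). At 4 hours Acta2 fell by 0.86 and Dcn rose by 0.85, both in the matrix list, and Abhd5, in the lipolysis list, rose by 0.58. These genes were chosen after their values were seen.

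A hypothesis was that peaks raised by both forskolin and rosiglitazone at 3 days lie near PPAR target genes more often than peaks raised by forskolin alone. Of 1024 shared peaks 15 (1.46%) were assigned to genes of the PPAR list, against 8 of 9079 (0.0881%) raised by forskolin alone. The odds ratio was 16.8 (95% interval 6.69 to 46.1, Fisher's exact test), and 13.4 (5.04 to 38) with 12 peaks when Plin2, the gene with most of them, was left out. The prediction was written before this odds ratio but after the rise of the PPAR list with rosiglitazone had been seen, and the shared peaks were picked for a rise with rosiglitazone, so the enrichment against forskolin alone follows at least in part from that selection. Against the 2810 peaks raised by rosiglitazone alone, of which 60 (2.14%) lay at PPAR genes, the odds ratio was 0.681 (0.358 to 1.22). For the thermogenic list it was 3.72 (1.58 to 8.1) against forskolin alone. Peaks of a gene are not independent, which makes these intervals too narrow. These tests therefore do not decide the hypothesis: nothing beyond the selection was seen at shared peaks.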
